A study of Oryza sativa with 8 samples.

How the data were processed

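RNA from 4 organs of the rice cultivar Ilmi (Oryza sativa) was measured on a long-oligomer array made to distinguish splice forms, with 2 arrays per organ and 8 arrays in all. Per the labels' protocols, leaves and roots came from plants 14 days after sowing, panicles were collected at a length of 0.5 to 1.5 cm before pollination, and ripening grains were collected 20 to 30 days after pollination; the seed sample is titled 21 days after pollination. The labels number the arrays of each organ as replicates 1 and 2 and do not say whether they came from separate plants, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, Cy3-labelled cRNA was made from 0.2 µg of total RNA.

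Each array was deposited as a scanner file with 180046 spots, of which 175192 were probes and 4854 were control spots. Per the file headers, signals were extracted with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name version 10.7.3.1. The deposited intensity used here was the processed signal of the single green channel, which the scanner software had already corrected for background and which had not been normalized between arrays. The deposited median spot intensity and median background intensity were used for one alternative. The authors also deposited a value table of 46411 targets with linear intensity values, combined over the probes of a target. Its medians lay between 455 and 469 in the 8 columns, and its log2 values correlated across targets with the scanner values of the same arrays at r between 0.969 and 0.975. Its normalization method is not given in the sources used here, and it served as an alternative.

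The probes named 41954 transcripts of 37868 numbered loci, of which 34237 had 1 transcript on the array and 3631 had 2 or more. A further 189 probes stood for 160 protein accessions, and 16 probes stood for 4 transgene markers. Some 25092 probes carried the suffix UE behind a single transcript's number; the suffix is not explained in the sources used here. The scanner files held transcript numbers without gene names, so a locus was derived from its transcript number. The deposited files pair no locus with a name. Locus and name pairs for 91 genes, and the lists they belong to, were written from published rice nomenclature before the data were examined. They were then checked against the NCBI RefSeq gene table of assembly ASM3414082v1, which holds no such locus numbers, so the check covered the name, its chromosome and its order along it. By that check 63 pairs matched, 4 of them through an alias, 23 names were not in the table, 2 were ambiguous and 3 conflicted and were dropped. Only the 63 are named in the text; lists were tested with all members except the 3. The 20 lists or parts of lists that were defined by words in a description could not be applied. The header names the rice build IRGSP5, which differs from that of the table, and no coordinates are given.

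The processed intensity was put on the log2 scale and the 75th percentile of all probes of the array was subtracted. Levels below are these relative log2 levels. Spots flagged as non-uniform or as outliers, 1289 values in all and 902 of them on panicle array 2, were set aside, and no probe was saturated on any array. A probe was kept when it was well above background on both arrays of at least 1 organ, which left 152384 probes of 35788 genes, and a gene's level was the mean of its kept probes (median 4). Where no kept probe of a gene was well above background on any array of an organ, or the gene's mean there lay below the lowest signal well above background, only a bound is given; the second condition was added after the values had been seen. It is written as at least N-fold: the mean of the brighter organ against the mean, in the dimmer organ, of the higher of the probe's own signal and the lowest signal of a probe well above background on that array.

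Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit over the 8 arrays, with 6 contrasts between organs and Benjamini-Hochberg adjustment within each contrast. A gene was called at an adjusted p under 0.05 and a log2 difference of at least 1. It was called organ-enriched when it was higher in that organ in all 3 contrasts that involve it, and lowest in the organ when it was lower in all 3. Probe usage, meaning a probe whose organ difference departs from that of the other probes of its locus, was tested with limma's diffSplice and the Simes method on probes well above background on at least 1 array of each organ. This covered 120476 probes of 28236 genes, each organ being set against the mean of the other 3. Lists of at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with the adjustment over all 20 pairs of list and organ. Tested on simulated data for 35773 genes, the calls of organ-enriched genes recovered 9 of 13 changed genes in leaf, 5 of 12 in root, 8 of 13 in panicle and 6 of 12 in seed at a log2 size of 2, and 10 of 12, 13 of 13, 10 of 12 and 12 of 13 at a size of 4, too few to rank the organs, with 0 false calls in leaf, root and panicle and 3 in seed. Probe usage at a size of 2 was recovered in 23 of 25 genes in leaf, root and panicle and 24 of 25 in seed, with 18, 76 and 75 false calls among 28236 genes for leaf, root and panicle and 3506 for seed. With 1 variance weight per organ the false calls were 175, 131, 146 and 151, and 25, 24, 24 and 18 of 25 genes were recovered in the same order; at a size of 1 recovery in seed fell from 13 to 8 of 25. The organ weights, estimated with limma's arrayWeights, were therefore added after the data had been seen. At the gene level the weights were 3.87 for leaf, 1.26 for root, 1.33 for panicle and 0.155 for seed. In the simulated data only a small share of genes was given the tested difference, far below the share called in the real data. Recovery and false calls may thus differ in the real data.

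Named genes followed a rule fixed before the data were examined. For each organ it took the 10 named organ-enriched genes with the largest smallest difference over the 3 contrasts, and the 3 genes lowest in that organ. It also took up to 4 examples per list, the 5 named genes with the smallest adjusted p for probe usage, and 3 loci listed as splicing examples. In leaf only 5 named genes were enriched. Floral regulators outside the rule were named after their values had been seen, as the text says.

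The arrays lay on 3 slides, each scanned on its own occasion. Slide 1 held both leaf arrays, root 1 and panicle 1. Slide 2 held root 2 and panicle 2. Slide 3 held both seed arrays and nothing else, so slide and organ cannot be told apart for seed. The block for slide had 1 term, for slide 2, which rests on root and panicle. It left the seed slide unadjusted in every value that involves seed. The 75th percentile of signal was 2024 and 1742 in leaf, 2350 and 2207 in root, 2897 and 2993 in panicle and 3288 and 1876 in seed, and between 76.7% and 82.2% of probes were well above background. The number of arrays limits the precision. Alternatives were another background correction (normexp with an offset of 50, on the median signal because the mean signal was not a column of the files), quantile normalization, median centring, a block for replicate number or slide, leaving out each array, another variance model, the authors' table, other probe filters, other thresholds, other ways to combine probes, other tests of lists and probe usage, and the organ weights.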

Results

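Transcript levels were compared between leaf, root, young panicle and ripening seed of rice, with 2 arrays per organ, to find genes and splice forms specific to an organ. Replicate arrays correlated across genes at r = 0.9977 in leaf, 0.9956 in root, 0.9951 in panicle and 0.978 in seed, against 0.706 to 0.794 between arrays of different organs. The replicate SD was 0.155 log2 units in leaf, 0.216 in root, 0.24 in panicle and 0.452 in seed. Of the 35788 genes tested, 28264 (79%) differed between at least 1 pair of organs, and 13342 (37.3%) were enriched in a single organ. The reference gene EEF1A, a translation elongation factor, had relative log2 levels of 6.01 in leaf, 6.02 in root, 5.93 in panicle and 5.92 in seed, and the actin gene ACT1 had 5.38, 5.67, 5.64 and 4.67.

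Leaf was marked by genes of carbon fixation and light harvesting. All 14 measured members of the photosynthesis list, 4 of them with a checked name, were enriched in leaf, over all genes and when adjusted over the list alone, and so were both members of the photorespiration list. RCA (Os11g0707000), which encodes Rubisco activase, stood at 6.43 ± 0.09 in leaf (SD, n = 2) and at 0.48 ± 0.33 in seed, the next highest organ, a 61.9-fold difference (log2 5.95, SE 0.17, adjusted p = 2.8e-06). RBCS2 (Os12g0274700), a small subunit of Rubisco, was 7.7-fold higher in leaf than in seed (adjusted p = 9.3e-05). The chlorophyll-binding protein genes CAB2R and CAB1R were 11.3-fold and 2.22-fold higher in leaf than in seed, with adjusted p of 0.00012 and 2e-04. GLO1, which encodes the photorespiratory enzyme glycolate oxidase, was 3.44-fold higher (adjusted p = 8.7e-05). The 3 tested probes of CAB2R disagreed, with 1 at 2.29 log2 units against the others in its leaf difference and at -3.67 in its root difference. Probes of GLO1 and RCA also disagreed, as given below.

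The photosynthesis list had a median leaf difference of 5.87 log2 units from the mean of the other organs (camera, adjusted p = 5e-11). With an estimated correlation the adjusted p = 0.17, so that call was lost, while with limma's fry, a rotation test, the adjusted p was 3.3e-06. With the slide as a block the median was 5.92 (adjusted p = 1.8e-10), and within slide 1 the list's median difference was 8.42 between leaf and root and 6.34 between leaf and panicle. In seed the same list was 1.87 above the mean of the other organs, though all 14 members were lower there than in leaf (adjusted p = 7.2e-05; adjusted p = 0.28 with an estimated correlation), and all 14 members were higher in seed than in root. In all, 3003 genes (8.4%) were enriched in leaf, 79 of them not well above background in any other organ, and 968 were lowest there. With the slide as a block 2976 genes were enriched in leaf. Among loci that could not be named, Os08g0139700 was at least 2565-fold higher in leaf than in seed, and Os03g0843800 at least 2101-fold higher than in root. Os11g0255300 was at least 10.5-fold lower in leaf than in panicle, and Os02g0572600 was 41.5-fold lower.

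Root was marked by genes of nutrient and water uptake. All 16 measured members of the root uptake list, 13 of them with a checked name, were enriched in root, over all genes and when adjusted over the list alone. TIP2;1 (Os02g0658100), a vacuolar aquaporin, stood at 6.5 ± 0.04 in root (SD, n = 2) and at -3.97 ± 0.42 in seed, a 1412-fold difference (log2 10.46, SE 0.23, adjusted p = 7.5e-07). The iron-handling genes NAS2 and NAS1, which encode nicotianamine synthases, were 400-fold above leaf (adjusted p = 5.4e-07) and 36.4-fold above seed (adjusted p = 2e-06). NAS1 was at least 8109-fold higher in root than in panicle. YSL15, which encodes an iron-phytosiderophore transporter, was at least 131-fold above leaf (adjusted p = 3.8e-07). The nitrate uptake genes NAR2.1 and NRT2.1 were 290-fold and 161-fold above leaf. The silicon transporter genes LSI2 and LSI1 were 55.4-fold above seed and 34.9-fold above leaf. The 3 tested probes of LSI2 disagreed. Against the others, 1 lay at -5.36 log2 units in its root difference and at 5.23 in its seed difference. Probes of AMT1;1, YSL15, PIP2;3 and IRT1 also disagreed, as given below. Of the 4 tested probes of NAS2, 1 lay at 2.32 log2 units against the others in its panicle difference. The aquaporin genes PIP2;3 and PIP2;5 were 55-fold above leaf and 12.9-fold above seed. The iron transporter gene IRT1 was 7.06-fold above seed (adjusted p = 1.9e-05) and the ammonium transporter gene AMT1;1 was 2.51-fold above leaf (adjusted p = 5.7e-05).

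The root uptake list had a median root difference of 7.22 log2 units (camera, adjusted p = 2.1e-10; adjusted p = 0.04 with an estimated correlation). It was 7.07 with the slide as a block (adjusted p = 2.8e-10). Its median difference between root and panicle was 8.4 within slide 1 and 8.24 within slide 2. Of 3 root development genes 1 was enriched in root; WOX11, a homeobox gene of crown root formation, stood at -6.4 ± 0.29 in root and -4.17 ± 0.42 in seed. In all, 3742 genes (10.5%) were enriched in root, 206 of them not well above background elsewhere, and 2429 were lowest there. The lowest of these by the rule were CAB1R and the anther gene UDT1, with log2 differences of -4.74 and -3.8 from the next lowest organ, and the floral gene MADS58, at least 6.7-fold lower in root than in leaf. With the slide as a block 3567 genes were enriched in root. Among unnamed loci, Os04g0629200 was 3880-fold higher in root than in seed and Os10g0335000 at least 854-fold higher than in leaf. Os03g0197100 was at least 426-fold and Os12g0563600 at least 293-fold lower in root than in seed.

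Young panicle was marked by cell division genes, by genes of germ cells and anthers, and by part of the floral regulators. All 3 measured cell division genes were enriched: CDKB2;1 and CDKB1;1, mitotic cyclin-dependent kinases, were 5.43-fold and 4.46-fold above leaf (adjusted p = 0.00012 and 5.8e-05), and the replication factor PCNA was 3.86-fold above leaf (adjusted p = 0.00045). MEL1 (Os03g0800200), an Argonaute gene of germ cells, stood at 2.81 ± 0.09 in panicle (SD, n = 2) and -2.34 ± 0.26 in seed, a 35.5-fold difference (log2 5.15, SE 0.14, adjusted p = 1.8e-06). UDT1 and TDR, regulators of the anther tapetum, were 2.39-fold and 2.34-fold above leaf (adjusted p = 0.0033 and 0.0079); without seed array 1 UDT1 was 1.91-fold above seed and lost its call. Of 17 floral regulators 7 were enriched in panicle, over all genes and when adjusted over the list alone. MADS34 was 14.5-fold above seed (adjusted p = 0.0012), where its SD was 1.32; without seed array 1 it was 27.8-fold and without seed array 2 7.6-fold above seed. DL, a gene of carpel identity, was 5.94-fold above leaf (adjusted p = 0.00019), and MADS18 5.23-fold above seed (adjusted p = 6.3e-05). The 3 tested probes of DL disagreed, with 1 at 3.07 log2 units against the others in its root difference and at -1.58 in its panicle difference. MADS5 was 5.07-fold, MADS14 at least 2.38-fold, MADS15 4.41-fold and MADS6 2.93-fold above seed. MADS14 was dim, at -5.2 in panicle. The probes of MADS15 and MADS16 disagreed: by the brightest probe alone, panicle minus the mean of the other organs was -0.85 for each (adjusted p = 0.013 and 0.024).

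The other 10 floral regulators did not pass in all 3 comparisons; except for MADS7, MADS13, MADS16 and MADS58, which the rule picked, those named here were chosen after their values were seen. MADS1 was at 2.99 ± 0.06 in panicle and 3.05 ± 0.38 in seed (log2 difference -0.06, SE 0.18, adjusted p = 0.78), and MADS2 at 1.5 and 1.54. MADS7, MADS8, MADS13, MADS58 and MADS3 were 3.49-fold, 3.96-fold, 8.03-fold, 10.4-fold and 17-fold higher in seed than in panicle, with adjusted p of at most 6.8e-05. The 3 tested probes of MADS13 disagreed, with 1 at 6.22 log2 units against the others in its seed difference. For MADS4, MADS17 and MADS16 the ratio of panicle to seed was 1.98, 1.61 and 1.4, below the threshold of size; without seed array 1 MADS4 passed it at 2.58. Against root, 16 of the 17 were higher in panicle and 16 were higher in seed; MADS7 was at least 736-fold above root in panicle. The list's median difference was 4.6 log2 units in panicle (camera, adjusted p = 1.4e-06; adjusted p = 0.17 with an estimated correlation) and 3.84 in seed (adjusted p = 2.8e-06; adjusted p = 0.17 with an estimated correlation). With dim probes set to the lowest signal well above background they were 3.88 and 3.77. The medians were 4.52 (adjusted p = 2.5e-06) and 3.85 (adjusted p = 7.4e-06) with the slide as a block. Between root and panicle its median difference was -6.64 within slide 1 and -6.34 within slide 2. In all, 3734 genes (10.4%) were enriched in panicle, 146 of them not well above background elsewhere, and 3253 were lowest there. The lowest of these by the rule were NAS1 and the seed albumin genes RAG2 and RA17, at least 64.5-fold and 23.7-fold below leaf and at least 5.03-fold below root in that order. With the slide as a block 3674 genes were enriched in panicle. Among unnamed loci, Os10g0315400 was at least 446-fold and Os10g0111800 at least 328-fold higher in panicle than in leaf. Os06g0486400 was at least 302-fold lower in panicle than in seed, and Os04g0523600 at least 173-fold lower than in leaf.

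Ripening seed was marked by storage protein and starch genes. All 10 measured seed storage genes, 9 of them with a checked name, were enriched, over all genes and when adjusted over the list alone. GLUA3 (Os03g0427300), a glutelin gene, stood at 7.32 ± 0.55 in seed (SD, n = 2) and -6.69 ± 0.22 in root, a 16414-fold difference (log2 14, SE 0.4, adjusted p = 1.6e-06). Its root level lay close to the lowest signal well above background on root arrays 1 and 2 (-6.81 and -6.89), so the size of this fold is uncertain. The glutelin genes GLUB5 and GLUB4 were 5069-fold and 4375-fold above root, and GLUD1 at least 5705-fold, with adjusted p of at most 4.9e-06; all 3 were not well above background in leaf and panicle. The SD of GLUD1 in seed was 1.11, and its bound over root was 9843-fold without seed array 1 and 3306-fold without seed array 2. GLUB2, GLUA1 and the albumin genes RA17 and RAG2 were between 405-fold and 2600-fold above the next highest organ, GLUA1 at 1165-fold above root, or 1989-fold without seed array 1 and 683-fold without seed array 2. The 2 tested probes of GLUA1 disagreed, with 1 at -4.02 log2 units against the other in its panicle difference. Of 12 starch genes, 7 of them with a checked name, 11 were enriched. WX (Os06g0133000), the granule-bound starch synthase, stood at 6.95 ± 0.42 in seed and -6.48 ± 0.04 in leaf, a difference of at least 9251-fold (adjusted p = 9.8e-07). The starch synthase genes SSIIa and SSI were 119-fold and 9.11-fold above panicle (adjusted p = 2.2e-05 and 2.1e-05), and ISA1, a debranching enzyme gene, was 57.8-fold above leaf (adjusted p = 2.1e-06). The 3 tested probes of SSIIa disagreed, with 1 at -3.47 log2 units against the others in its seed difference. The member that did not pass was PPDKB, a pyruvate phosphate dikinase gene, with a ratio of seed to leaf of 1.88, below the threshold of size. Without seed array 1 the ratio was 2.09. This level pools targets named for 2 transcripts, whose log2 difference (01 minus 02) was 1.83 in leaf and -2.48 in seed, as given below. The 3 endosperm regulators were enriched, among them NFYB1 at 1262-fold above root (adjusted p = 5.8e-07), as were both embryo genes, among them the oleosin gene OLE18 at 2777-fold above root (adjusted p = 1.5e-06).

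The seed storage list had a median seed difference of 14.08 log2 units (camera, adjusted p = 1.6e-07; adjusted p = 0.21 with an estimated correlation) and the starch list one of 7.29 (adjusted p = 1.1e-07; adjusted p = 0.23 with an estimated correlation). With dim probes set to the lowest signal well above background they were 12.72 and 7.19. The medians were 13.92 (adjusted p = 7.3e-07) and 7.36 (adjusted p = 3.5e-07) with the slide as a block. In root all 10 storage genes had a probe well above background on at least 1 array. In all, 2863 genes (8%) were enriched in seed, 224 of them not well above background elsewhere, and 1287 were lowest there, among them CDKB2;1 with a log2 difference of -1.08 from the next lowest organ. Without seed array 2 that call was lost, as CDKB2;1 was then 1.67-fold lower than in root. Seed arrays lay on a slide of their own, so organ and slide cannot be told apart. With the slide as a block 2914 genes were enriched in seed, but that block did not adjust for the seed slide. The main fit used the same variance per gene for all organs, although the seed arrays varied most. With organ weights 2913, 3532, 3526 and 2521 genes were enriched in leaf, root, panicle and seed. Among unnamed loci, Os03g0336100 was at least 9307-fold higher in seed than in panicle and Os07g0615500 at least 12472-fold higher than in root. Os07g0535100 was at least 18.3-fold lower in seed than in leaf and Os01g0824900 at least 21.9-fold lower than in root.

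**Figure D1:**
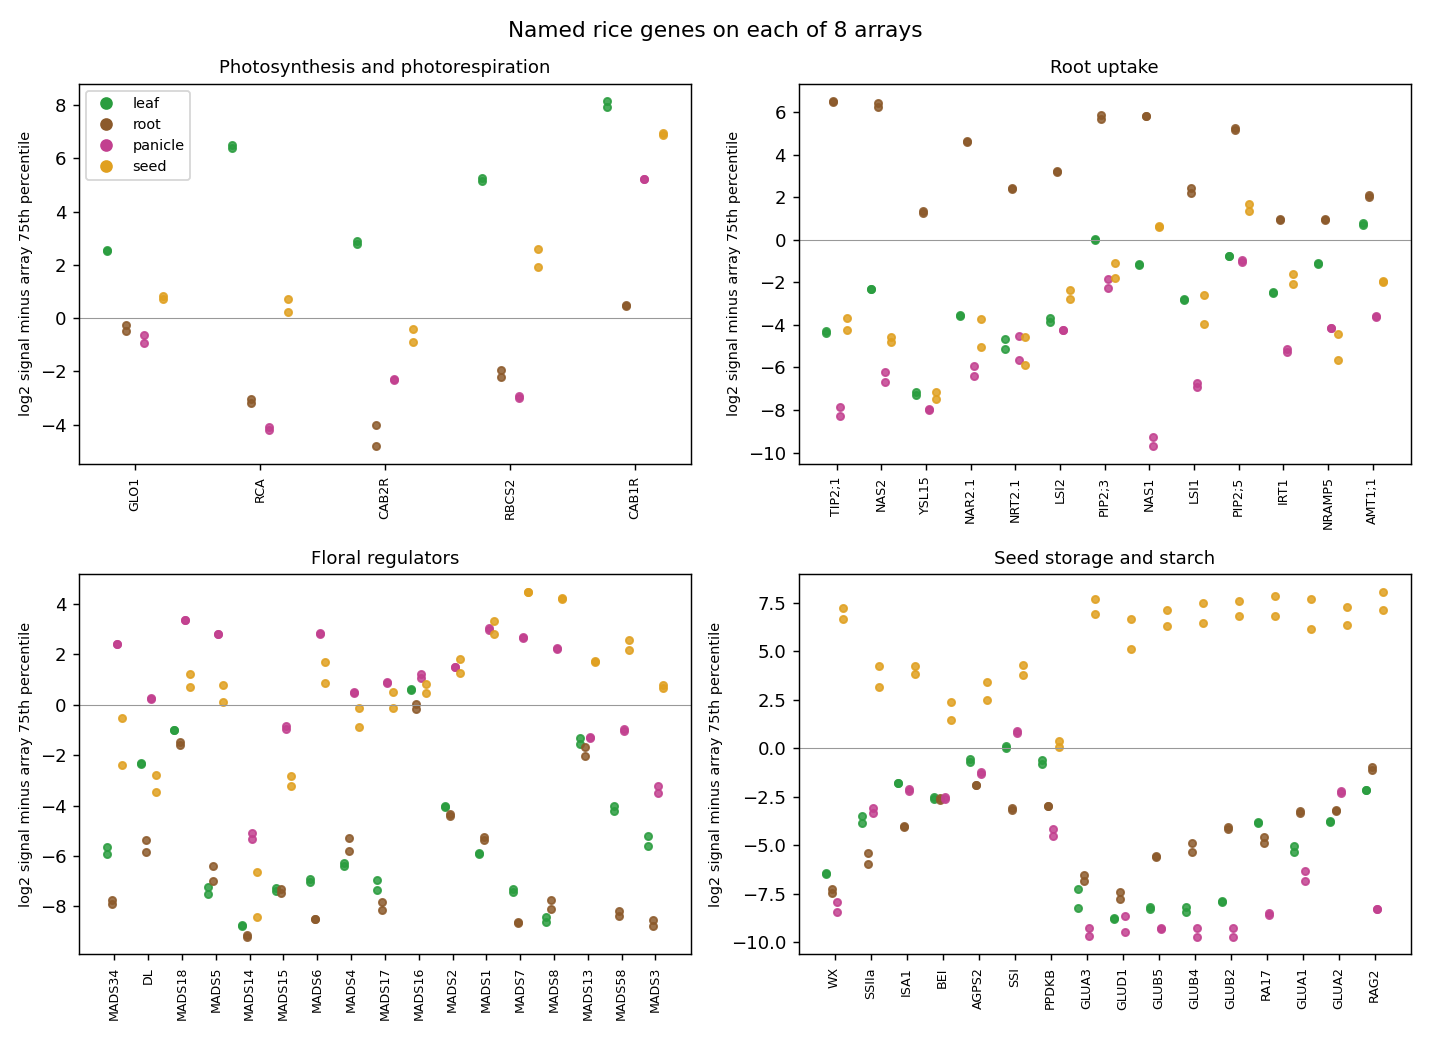
Relative log2 signal (vertical axis, log2 signal minus the array's 75th percentile) of named genes in 4 lists, with 1 point per array and colours for the organs. RCA is near 6.43 in leaf, TIP2;1 near 6.5 in root and GLUA3 near 7.32 in seed, each far above the other organs, while MADS1 is near 3 in both panicle (2.99) and seed (3.05).

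Pairs of organs differed in between 13505 and 18097 genes. Leaf and root had the fewest at this threshold, with 6390 genes higher in leaf and 7115 higher in root; at a log2 difference of at least 2, leaf and seed had fewer (7211 against 7553). Floral regulators separated panicle from leaf, with 15 of 17 higher in panicle, and photosynthesis genes separated leaf from panicle, with 14 of 14 higher in leaf. Leaf and panicle differed in 17604 genes, 8352 of them higher in leaf and 9252 higher in panicle. Root and panicle differed in 18097 genes, 8703 higher in root and 9394 higher in panicle. Against seed, leaf differed in 15447 genes (6923 higher in leaf), root in 15653 (7088 higher in root) and panicle in 15683 (6883 higher in panicle). With organ weights these seed comparisons gave 14209, 14465 and 14330 genes in the same order. Of the 12 starch genes, 11 were higher in seed than in leaf and 12 were higher in seed than in either root or panicle.

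With the slide as a block the counts were 13153 for leaf and root, 17456 for leaf and panicle and 18041 for root and panicle. They were 15312 for leaf and seed, 15440 for root and seed and 15740 for panicle and seed. The counts with seed were not adjusted for the seed slide, which held no other organ. Root and panicle were both on slides 1 and 2: of the genes called between them, 98.2% differed by at least 1 log2 unit in the same direction within slide 1 and 97.5% within slide 2, and the difference correlated between slides at r = 0.991 across genes, which are not independent replicates. Within slide 1 the same held for 97% of genes called between leaf and root and 97.4% of those called between leaf and panicle. These genes were called with the same arrays. Which organ of a pair had more of the higher genes depended on the processing and the threshold. With quantile normalization the share higher in the organ named first went from 43.9% to 54.1% for panicle and seed, from 45.3% to 51.2% for root and seed and from 44.8% to 50.2% for leaf and seed. The authors' table also turned these 3 pairs, to 53%, 50.7% and 51.1%, and median centring turned panicle and seed (51.1%). At a log2 difference of at least 2 the share was 52.7% for leaf and root, 62.9% for leaf and panicle, 56.9% for root and panicle and 50.2% for leaf and seed. With normexp on the median signal, which changed the background step and the intensity column together, the share went from 47.3% to 51.1% for leaf and root, from 47.4% to 55% for leaf and panicle, from 48.1% to 52.2% for root and panicle and from 44.8% to 52% for leaf and seed.

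**Figure D2:**
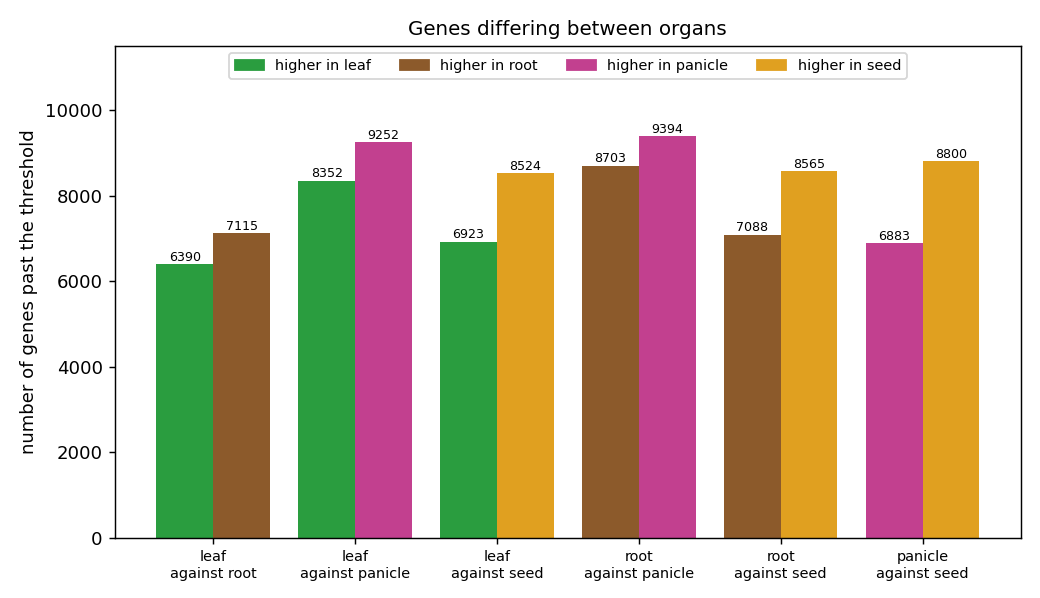
Number of genes (vertical axis) past the threshold in each of the 6 comparisons, with a bar for genes higher in each organ of the pair. Bars range from 6390 genes (higher in leaf than in root) to 9394 genes (higher in panicle than in root).

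Single probes of a locus often changed differently from the other probes of that locus. The genes given here ranked first only among those with a checked name, not among all genes tested. In leaf, GLO1 and the ammonium transporter gene AMT1;1 had the smallest adjusted p of these (2.8e-16 and 2.9e-14). Probe 9 of GLO1 was 6.12 log2 units above the other probes of the locus in its leaf difference, and a UE probe of AMT1;1 lay at -3.22. PPDKB, MADS16 and RCA followed (4.9e-13, 5.2e-09 and 6.4e-09). In root AMT1;1, GLO1, YSL15, PIP2;3 and IRT1 led, the probe of PIP2;3 at 6.76 and that of YSL15 at -5.84. In panicle the same rule gave AMT1;1, GLO1, IRT1, RCA and MADS15, with a UE probe of MADS15 at -7.03 (adjusted p of the probe = 4.7e-08). Only 2 probes of MADS15 were tested, so which of the 2 departed cannot be told. In seed the rule gave BEI, GLO1, AMT1;1, AGPS2, a subunit of ADP-glucose pyrophosphorylase, and MADS13, with probes at -4.61 for BEI and 6.22 for MADS13. Of the listed splicing examples, RCA passed in all 4 organs and DREB2B, a stress-response transcription factor, in none (smallest adjusted p = 0.61); WX did not have probes that could be tested.

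By limma's diffSplice 7981 of 28236 genes (28.3%) passed in leaf, 7868 (27.9%) in root, 7925 (28.1%) in panicle and 11234 (39.8%) in seed; with the slide as a block the counts were 7494, 7595, 7852 and 10859. Where a probe difference of at least 1 log2 unit was also required, 4534, 4793, 4882 and 5039 passed. The seed arrays had the widest spread, and the seed count fell to 3241 with organ weights, all of them among the 11234; the same step gave 10584 in leaf, 8223 in root and 8726 in panicle. In simulated data these weights removed false calls in seed but also true ones, with 18 in place of 24 of 25 recovered at a log2 size of 2. Single arrays moved these counts: leaf had 4323 and 4426 calls without leaf array 1 or 2 and 12269 and 12706 without seed array 1 or 2, root had 11803 without seed array 2, and panicle had 5155 without panicle array 1.

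Targets named for single transcripts of a locus, those with the suffix UE, often differed by another amount from organ to organ; that each measures its splice form alone is not stated in the sources used here. The target of PPDKB transcript 01 minus that of transcript 02 was 1.83 ± 0.06 log2 units in leaf (SD, n = 2), -3.9 ± 0.07 in root, -3.36 ± 0.36 in panicle and -2.48 ± 0.16 in seed (limma moderated F, adjusted p = 1.7e-06). For RCA, which is known to give splice forms, the same difference was 1.64 in leaf and 1.8 ± 0.65 in seed, against -0.7 ± 0.58 in root and -1.94 ± 0.33 in panicle (adjusted p = 7.2e-05). For BEI it was -2.82 ± 0.17 in seed and between -1.23 and -0.58 in the other organs (adjusted p = 0.0036). Only the change of such a difference between organs is a measurement, since probes differ in brightness. The F test of these differences across the 4 organs used the organ weights. Of 2537 loci with 2 such targets, 1214 (47.9%) changed by at least 1 log2 unit at an adjusted p under 0.05. Without organ weights 1230 did. The F test was chosen after the probe names had been seen. The comparison set below was redrawn with matched signal after a first version had been seen. With at most 2 probes per target 49.7% changed, against 17.2% of 2537 loci with 1 transcript whose probes were drawn in the same numbers and at matched signal (odds ratio 4.75, 95% interval 4.17 to 5.42, Fisher's exact test, p = 1.3e-136). All loci were measured on the same 8 arrays and are not independent replicates, so the interval and p do not measure replication.

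**Figure D3:**
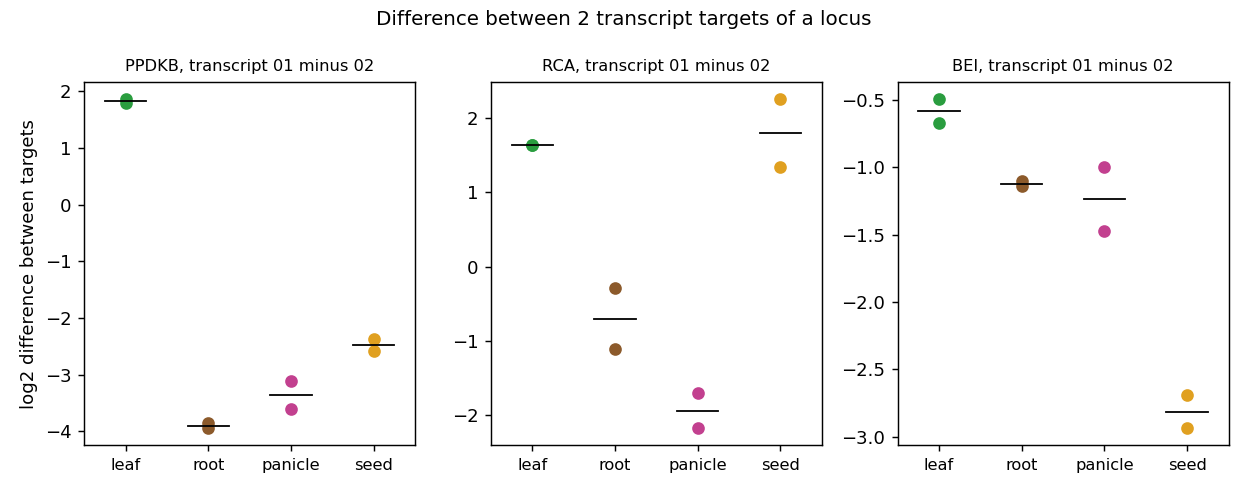
Log2 difference between the targets named for transcripts 01 and 02 (vertical axis) of PPDKB, RCA and BEI in the 4 organs, with 1 point per array and a line at the mean. The PPDKB difference is 1.83 in leaf and lies between -3.9 and -2.48 in the other organs.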

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

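Probes for 4 transgene markers, which no comparison of the report used, gave signal well above background on part of the arrays. This held for 23 of 32 spots of sGFP, 11 of 24 of Bar, 7 of 40 of Hygromycin and 6 of 32 of Knamycin, against 58 of 4800 negative control spots (1.21%). Bar, Hygromycin and Knamycin stayed dim, with highest signals of 45.6, 66.8 and 53. The 4 sGFP probes had a mean relative log2 level of -3.63 ± 0.01 in panicle (SD, n = 2), -6.66 ± 0.49 in leaf, -6.69 ± 0.5 in root and -6.31 ± 0.08 in seed. The brightest sGFP probe had a mean signal of 1004 in panicle and between 41.3 and 59.1 in the other organs. The labels mention no transgene, and no explanation was tested.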

How the results depend on the processing

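The organ weights, the list with only name-matched members, the fit without seed arrays, the folds of single genes without 1 array and every alternative of the isoform test were chosen after the data had been seen; the others were fixed before. Over other settings that stayed within 1.5 times, organ-enriched counts ran from 2379 to 4133 in leaf, 2963 to 5572 in root, 2581 to 4418 in panicle and 2106 to 2914 in seed. Other thresholds and units moved counts by construction. With a log2 difference of at least 2, enriched genes numbered 1711, 2085, 1119 and 1540 in leaf, root, panicle and seed; with each probe as a unit the figures were 13200, 14629, 16281 and 11356 probes. With no fold threshold, panicle had 7427 and seed 4688. With only probes well above background on all 8 arrays, root had 2468 and seed 1804. For pairs, a log2 difference of at least 2 gave 7553 (leaf and root), 8272 (leaf and panicle), 7211 (leaf and seed), 9752 (root and panicle), 8290 (root and seed) and 7826 (panicle and seed) genes; each probe as a unit gave 57562, 76912, 68280, 77157, 67450 and 66593 probes in the same order. No fold threshold gave 21432 (leaf and root), 24060 (leaf and seed), 23879 (root and seed) and 24325 (panicle and seed). Deviations of same-numbered arrays correlated at 0.057 to 0.426 and not all above 0.1, so the numbers were not taken to pair the samples; the highest value was that of root and panicle, whose same-numbered arrays shared a slide. With the replicate block 3000, 3751, 3738 and 2882 genes were enriched in leaf, root, panicle and seed and 9116, 8813, 8880 and 12628 passed for probe usage. Leaving out 1 array at a time gave 2833 to 3081, 3510 to 3800, 3527 to 3877 and 2717 to 3382 enriched genes; 12814 to 13666, 16929 to 17716, 14555 to 16284, 17543 to 18203, 15085 to 16229 and 14877 to 16803 for pairs in the order above; probe usage ran from 4323 to 12706 in leaf, 5318 to 11803 in root, 5155 to 11668 in panicle and 8265 to 14748 in seed; isoform calls from 1138 to 1300; and list calls from 19 to 20 of 20. The lone array was assumed to vary like the other organs. Without both seed arrays 13666 (leaf and root), 17716 (leaf and panicle) and 18203 (root and panicle) genes were called, the same counts as without either, since a lone array adds nothing to the spread. Probe usage fell to 2119, 2403, 2465 and 2704 in leaf, root, panicle and seed with the authors' table, which has targets in place of probes, to 4534, 4793, 4882 and 5039 with a probe difference of at least 1, and to 3241 in seed with organ weights, where simulated data without weights gave 3506 false calls. Keeping saturated probes changed nothing, as there were none. With an estimated correlation 2 of 20 list calls were left, both of root uptake (root and panicle), and 18 kept their direction and lost the threshold. Correlation among members was not the only reason. The root uptake list had an estimated correlation of -0.03, and its adjusted p by camera in leaf still went from 0.02 to 0.17. With fry, which does not set a list against the other genes, all 20 calls were kept. In panicle the starch list (-1.37) lost its call with normexp (adjusted p = 0.052), the slide block (0.056) or without panicle array 2 (0.055). With only probes well above background on all 8 arrays, the root uptake list in leaf (-1.06) lost its call, as did root uptake (-0.75) and starch (-1.09) in leaf with only name-matched members; the latter left 14 calls among 16 pairs, as too few photosynthesis genes had a checked name. For 60 named genes the difference of the list's organ from the mean of the other 3 was followed by its adjusted p alone. This tests neither the calls of enrichment nor the folds given above. The sign turned in 3: MADS3 in panicle (-0.25 with normexp), and MADS15 and MADS16 in panicle (-0.85 each by the brightest probe). The cause was not tested. WOX11, which was not enriched in root, kept its negative direction there (-0.96 in the main fit). Its adjusted p rose above 0.05 with normexp (-0.39) and by the brightest probe (-0.16). Without root array 1 the difference was -0.75. The median difference of all genes moved by up to 0.29 with normexp on the median signal (leaf minus panicle) and 0.25 with quantile normalization (panicle minus seed); the main medians lay between -0.19 and -0.07. Signal over background limits low genes, and folds against dim organs depend on the background correction.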

Other observations

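The tests on the seed arrays in the second pattern below, and those of ripening stage and of signal-dependent scaling in the third, were chosen only after the result was seen; the others were written before. The group of accessions in the next paragraph was picked after its values were seen.

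Of 96 measured protein accessions with the prefix CAA, 84 were enriched in leaf and 95 were higher in leaf than in root, with median relative log2 levels of 4.79 in leaf, -1.22 in root, 1.27 in panicle and 1.72 in seed. The accessions could not be named from the sources used here. Markers of one organ were also readable in others: RAG2 and RA17 were well above background in leaf and root, and the seed storage list had a median log2 difference from the mean of the other organs of -1.81 in root and -7.21 in panicle, or -2.73 and -5.65 with dim probes set to the lowest signal well above background. Isoform calls were spread over the organs, with panicle farthest from the median of the organs in 367 loci, seed in 308, root in 306 and leaf in 233.

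Probe usage calls in leaf were common at loci with 1 annotated transcript: 5870 of 24689 (23.8%) passed, against 2106 of 3533 (59.6%) with 2 or more. Matched on the number of probes the odds ratio was 1.39 (95% interval 1.24 to 1.56), between the bounds set beforehand, so the part of annotated isoforms stays open. Among loci with 1 transcript whose probes were all above the median probe signal 15.8% passed, which leaves the signal floor of dim probes open as a part of the calls. A trend along the transcript stays open too: the leaf difference of the last minus the first probe had a median of 0.012 over 24668 loci, but with an SD of 0.79 loci went both ways, which the bound set beforehand had not allowed for, and no source used here says that probe numbers follow position. Unannotated splice forms or cross-hybridization may also contribute and were not tested.

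Seed arrays showed floral MADS-box and photosynthesis transcripts. Panicle RNA in the seed samples is argued against only at the share that MADS1 needs (seed minus panicle 0.06). The set was 102 genes above the 75th percentile and at least 4 log2 units higher in panicle than in leaf and root. Its median seed minus panicle was -3.81 (quartiles -5.64 and -2.1), and MADS7 was higher in seed than in panicle. A smaller share of panicle RNA stays open. Leaf RNA at the share that CAB1R needs (-1.15) is likewise argued against by a median of -3.73 over 618 leaf genes picked likewise. Leaf RNA at the share that the photosynthesis list's median needs (-3.33, or 9.93% of the leaf level) is also argued against, since the lower quartile of those genes was -4.7 and RCA stood at -5.95, or 1.62% of its leaf level; a smaller share stays open. With 0 arrays of other organs on the seed slide, slide and organ cannot be told apart, and expression in grain tissue itself stays open as untested.

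The seed arrays differed more from each other than those of other organs. A signal floor on the dimmer array is argued against, as in the top quartile of genes by signal the replicate SD was 0.316 in seed and 0.0499 in leaf, a ratio of 6.33. Seed array 1 minus array 2 had a median of 0.46 for the photosynthesis list, 0.51 for floral regulators and 0.69 for cell division. It was -0.93 for seed storage and -0.79 for starch, against -0.04 over all genes. For root uptake it was 0.14, inside the range of random lists of the same seed level (-0.36 to 0.3). Scaling that depends on signal is argued against for the storage list, whose -0.93 lay below 95% of 10000 random lists of the same seed level (-0.62 to 0.08). Grains at different ripening stages may differ in this way, but these values do not tell stage from other causes. The photosynthesis list lay above 95% of its random lists (-0.37 to 0.15), and its difference from all genes was 0.5035, only just past the bound of 0.5. Its members varied together (estimated correlation 0.6), unlike genes drawn at random, so any shared shift could place it there. Unequal small shares of leaf or panicle RNA, left open above, were not tested here. Both seed samples carry the title of 21 days after pollination, and the protocol gives 20 to 30 days. Whether they differed in stage within that range is not stated.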
